A study of Mus musculus with 25 samples.

How the data were processed

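Messenger RNA of mouse atria was measured by RNA sequencing in 25 libraries, 12 of wild-type mice and 13 of mice labelled as knockouts of Pam, the gene of peptidylglycine alpha-amidating monooxygenase. The labels give mice of 60 to 90 days, stranded TruSeq mRNA libraries, paired reads of 75 bases, a plan of 20 M reads per library and a single NextSeq run. Sex and genotype were taken from the labels, which gave 7 wild-type males, 5 wild-type females, 5 knockout males and 8 knockout females. The library names in the labels fall into 3 sets, called here after their words: the LARA set (names that begin with LA or RA, 12 libraries), the CGI set (9 libraries) and the MaleKOAtrium set (4 libraries, all of knockout males). Each set numbers its libraries from the start again. What the sets stand for is not given in the sources used here.

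Per the labels, the authors aligned the reads with HISAT2 to mm10, counted them with HTSeq and compared genotypes with DESeq2, with no versions stated. The deposited table holds 14467 lines of genes. The deposited values of single libraries are CPM, although the header calls the table FPKM. Every value (100% in the library with the lowest share, tolerance 0.001 reads) was a whole multiple of 1 step per library, the same for all genes, so no division by gene length had been made. The whole reads and the depth of each library were recovered from these steps. The authors' deposited table also gives the log2 ratio of the wild-type average over the knockout average and a p-value from DESeq2. Whether that p-value is adjusted, and which design gave it, is not stated. The lowest mean over the 25 libraries was 1.00 CPM, so genes below that level had been left out by the authors. For 5 symbols listed more than once, the MaleKOAtrium columns held equal values on both lines for 5 of 5 symbols and the other columns for 0, as a join of these columns to the rest by symbol would give. Whether these 4 libraries were counted with the same annotation as the rest is not given in the sources used here, which bears on every comparison with knockout males. The 10 lines of these symbols were left out, and 14457 genes remained. The 2 columns with the authors' averages per genotype were not used, since means were computed here from the single libraries.

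The unit differed from the FPKM foreseen, and the transformation planned for FPKM, log2 of the value plus a pseudocount of 1, was applied to the CPM. Genes needed at least 1 CPM in at least 5 libraries, which removed 0 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Differences are log2, knockout minus wild type or female minus male, with the standard error (SE) from limma. Group levels are the mean and standard deviation (SD) over libraries. The 6 comparisons were knockout against wild type over both sexes, in females and in males, female against male in wild type and in knockout, and the difference of the knockout effect between the sexes. The name set was a term in all fits except knockout against wild type in males, where 4 of 5 knockout males form a set of their own and the contrast with a set term rests on 1 knockout male. Pam itself was also compared with exact two-sided permutation tests of the log2 levels. Gene lists were tested with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 36 lists fixed, 33 had at least 5 measured members and were tested. Lists, comparisons, tests, the alternatives marked so below and the rule for named genes were set before the data were examined. Under that rule, Pam was always named, with the 10 genes of largest log2 difference among the called genes of each direction and up to 4 called members of each list. Where fewer than 5 genes of a direction were called, the genes of smallest p up to 5 were named as not passing, and of lists with no called member up to 2 were given with values. Some genes that the rule names are not reported here. Genes chosen outside this rule after their values were seen are marked so in the text, with these exceptions. Fkbp5, Per1, Hif3a, Tsc22d3, Rrm2, Birc5, Mki67, Nmrk2 and Tnc were named because they passed adjusted over their list alone. Upk1b, Tcf21, Myl7 and Nppb were also named after their values were seen.

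Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names, in which 14325 of the 14457 symbols (99.1%) were found. Depth ran from 2246887 to 8098602 reads per library with a median of 5385966. A floor of 3 reads corresponds to 0.370 CPM in the deepest library and to 1.34 CPM in the least deep. The floors cover counting error only, since reads are not independent molecules. The procedure was tested on simulated negative binomial counts, with 200 of 14457 genes changed. They had the depth of these libraries and the spread left after terms for group and name set. Genes were drawn independently, with no shift shared by a name set, a heart region or a library. Of 50 genes changed 2-fold, 74% were recovered in the comparison over both sexes, 72% in females, 60% in males and 66% between wild-type sexes. Of 50 genes changed 1.5-fold, 36%, 10%, 20% and 8% were recovered in these comparisons. Among 14257 unchanged genes, 10, 4, 5 and 6 were called. Other splits of the real male libraries called up to 2075 genes, so the simulated rates leave out structure that these data hold.

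Alternatives fixed beforehand were a pseudocount of 0.1, no filter or a mean of at least 5 CPM, median-ratio scaling, quantile normalization, arrayWeights, eBayes without trend or robust, other codings of the name set or none, single sets, only the compared groups, a replicate block for males, and leaving out each library in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads, edgeR with the name set as a term in males, Bmp10 as a covariate, and fits without WF10 and KM01 or without the 3 wild-type females of the CGI set. Permutations, Fisher's exact tests and figures used Python 3.11.15 with scipy 1.17.1, statsmodels 0.14.6, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.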

Results

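Messenger RNA of mouse atria was measured in 25 libraries to ask how the loss of Pam alters the atrial transcriptome. Pam encodes the copper-dependent enzyme that amidates the C-terminus of secreted peptides, and it is a major membrane protein of atrial secretory granules. The groups held 7 wild-type males, 5 wild-type females, 5 knockout males and 8 knockout females. Libraries carry the codes of the labels, with W or K for genotype, M or F for sex and a number. Depth was 4303451 to 7266010 reads in wild-type males, 2246887 to 7618482 in wild-type females, 2494461 to 8098602 in knockout males and 4597974 to 7376149 in knockout females. The LARA set held 4 wild-type males, 2 wild-type females, 1 knockout male and 5 knockout females, the CGI set 3 wild-type males, 3 wild-type females and 3 knockout females, and the MaleKOAtrium set the other 4 knockout males.

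Libraries of 1 group differed widely in genes that mark heart regions, of which Bmp10 and Myl2 were chosen after their values were seen. Bmp10, a growth factor gene of the right atrium, was at 7597 CPM in KM05 and at 46.5 CPM in KM01. It was at 0.433 CPM in WM1, 1.25 in WM2, 0.929 in WM3 and 1.26 in KF14, and at 1999 to 6180 CPM in the other 4 wild-type males. Myl2, the ventricular regulatory light chain, ran from 6.82 CPM in KM01 to 4724 CPM in WF10, and within knockout females from 10.9 to 3269 CPM. Mitochondrial genes gave 30.2% of the CPM in WF10 and 18.5% in KM01, the 2 least deep libraries.

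**Figure D1:**
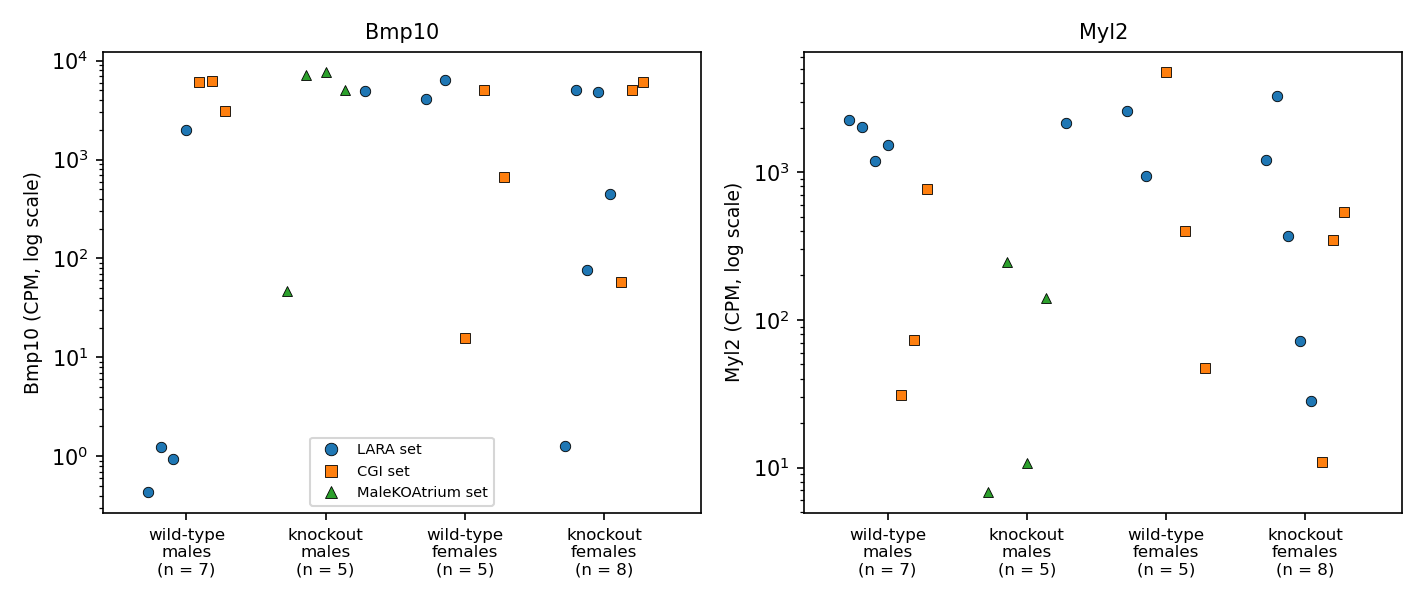
Level of Bmp10 (left) and Myl2 (right) in CPM on a log scale, 1 point per library, with marker shape and colour for the name set. Within each of the 4 groups the points spread over more than 10-fold, with Bmp10 at 0.433 to 1.26 CPM in WM1, WM2, WM3 and KF14 and Myl2 at 4724 CPM in WF10.

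Pam fell in every knockout library. In females it was at 425 ± 76.7 CPM (SD, n = 8) in knockouts and at 4513 ± 1950 CPM (SD, n = 5) in wild type, a 10.6-fold difference (log2 -3.25, exact permutation p = 0.00155, the smallest that 1287 splits can give). In males it was at 412 ± 56.7 CPM (SD, n = 5) and 4860 ± 1206 CPM (SD, n = 7), an 11.8-fold difference (log2 -3.53, exact permutation p = 0.00253, the smallest that 792 splits can give). The highest knockout library was at 520 CPM and the lowest wild-type library, WF10, at 1409 CPM. Within the LARA set the log2 difference was -3.39 in females and -3.23 in males, the latter from 1 knockout male, and within the CGI set it was -3.24 in females. Pam lies on the minus strand of chromosome 1 from 97795114 to 98095646 (GRCm38), and the part of the gene that was deleted is not given in the sources used here.

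**Figure D2:**
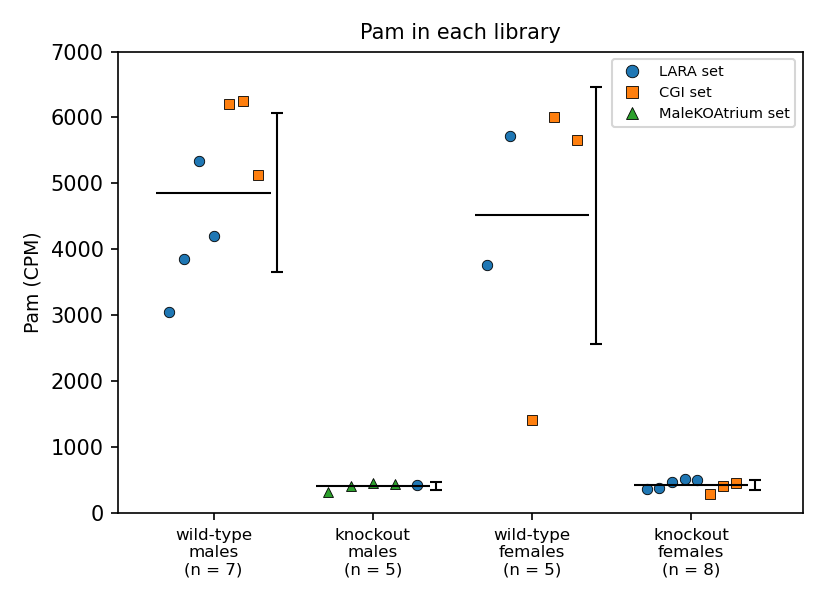
Pam in CPM, 1 point per library, by group, with marker shape and colour for the name set. Horizontal lines are group means and vertical bars are ± 1 SD, and all knockout libraries lie at or below 520 CPM while the lowest wild-type library is at 1409 CPM.

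Over both sexes, the comparison that the series was made for, Pam was the gene that changed (log2 -3.29 ± 0.24 SE, limma adjusted p = 1.99e-09). Of 14457 genes tested, 1 was called, and 532 had an unadjusted p under 0.05 where 723 would be met by chance. That number was above chance with other scalings and tools, at 950 with median-ratio scaling, 919 with quantile normalization, 995 with no name set term, 933 with edgeR and 1109 with DESeq2. With the name set as a term the MaleKOAtrium libraries did not enter the difference, which rested on 8 knockout females and KM13. Among genes that did not pass, Lrrc10, a regulator of cardiac contraction, had the smallest p of those higher in knockouts (log2 1.12 ± 0.21 SE, limma adjusted p = 0.119). It was at 89.7 ± 29.6 CPM (SD, n = 8) in knockout and 44.5 ± 16.1 (n = 5) in wild-type females. Males had 152 CPM in KM13, 53.3 ± 13.2 (n = 4) in the MaleKOAtrium set and 52.4 ± 15.5 (n = 7) in wild-type males. Others higher were Rarres2, which encodes chemerin (log2 0.95), the glucocorticoid-induced transcription factor Zbtb16 (1.78) and the endosomal protein gene Wdfy1 (0.72). Lower were the clock activator Arntl (log2 -1.57, adjusted p = 0.298), the mesenchymal transcription factor Prrx1 (-0.49) and Dock11 (-0.53). The count was 2 without WF9, 2 without KM13 and 3 without KM01.

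Gene groups close to the function of Pam had no call over both sexes. In the simulation, which held no shifts shared between genes, 36% of 1.5-fold changes were recovered in this comparison. Of 21 measured genes for atrial peptides and their receptors 0 passed, also when adjusted over the list alone, and the median log2 difference was -0.02 (mean 0.08, camera direction lower, limma adjusted p = 0.960). Nppa, the atrial natriuretic peptide gene, was at 1269 ± 257 CPM (SD, n = 7) in wild-type and 1799 ± 713 (n = 5) in knockout males, and at 1050 ± 317 (n = 5) in wild-type and 1375 ± 282 (n = 8) in knockout females, a log2 difference of 0.29 with adjusted p = 0.981. Secretory granule and prohormone processing genes (24 measured, median 0.10, adjusted p = 0.840), copper handling genes (26 measured, median 0.07, camera direction lower, adjusted p = 0.840) and known Pam interactors and relatives (11 measured, median -0.08, adjusted p = 0.0841) had 0 members that passed, over all genes or adjusted over the list alone. Of 34 precursors of amidated peptides only 5 were measured, Gnrh1, Nmb, Calcb, Adm and Npff, with a median of 0.37 (adjusted p = 0.319) and 0 called by either count. In these libraries most substrates of the enzyme were thus not among the genes that the authors kept. The lists named in this paragraph had no camera call in either sex alone (adjusted p = 0.0999 to 0.741 in females and 0.317 to 0.998 in males).

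With the preset correlation camera called 6 of 33 lists over both sexes, and 0 were kept with an estimated correlation (adjusted p = 0.813 to 0.867 with an estimated correlation). The lists lower in knockouts were erythroid genes (median -0.56, 8 of 8 lower), ventricle markers (-0.52), mitochondrially encoded genes (-0.16) and smooth muscle and pericyte markers (-0.17), each with 0 members called. The mitochondrial list was at -0.04 with quantile normalization. WF10 had the highest mean level of ventricle markers (7.72) and 30.2% of CPM from mitochondrial genes. Those higher were steroid receptors and their targets (median 0.29, 5 of 14 higher adjusted over the list alone and 0 over all genes) and clock genes (median 0.69, 11 of 19 higher and 4 lower adjusted over the list alone, 0 over all genes).

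In females, Pam and Wdfy1 changed. Wdfy1, whose product binds endosomal lipids and takes part in Toll-like receptor signalling, rose from 20.0 ± 6.59 CPM (SD, n = 5) to 38.4 ± 10.4 CPM (n = 8), a log2 difference of 1.02 ± 0.16 SE (limma adjusted p = 0.00796). The same direction held in both name sets, with 13.8 and 16.1 CPM in 2 wild-type libraries against 33.5 ± 7.60 CPM (SD, n = 5) in the LARA set and 23.4 ± 6.56 (n = 3) against 46.5 ± 10.4 (n = 3) in the CGI set. The median of all genes was shifted by 0.122 in this comparison and by 0.0106 after median-ratio scaling, which put Wdfy1 at 0.90 with adjusted p = 0.0577. Its adjusted p was 0.108 without WF8 and 0.0625 without WF12, each leaving 1 called gene, and over all alternatives it ran from 2.01e-05 (DESeq2) to 0.988 (LARA set alone). The difference of the knockout effect on Wdfy1 between the sexes was 1.38 (adjusted p = 0.233).

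Genes that did not pass in females included Rarres2 (105 ± 42.4 CPM SD, n = 5, in wild type and 225 ± 68.8, n = 8, in knockouts, limma adjusted p = 0.667), Lrrc10 (log2 1.01), the immunoglobulin light chain constant gene Igkc (-1.44), the circadian repressor gene Nfil3 (-1.28) and the myofibril gene Xirp2 (-0.85). Clock genes were also among them. Dbp, a clock output gene chosen after its values were seen, was at 38.1 ± 43.2 CPM (SD, n = 5) in wild type and 96.8 ± 24.1 (n = 8) in knockouts, Per2 at 12.9 ± 11.6 and 37.1 ± 10.5, and Arntl at 33.4 ± 24.5 and 7.75 ± 3.09. Of 19 clock genes, 11 were higher and 3 lower adjusted over the list alone and 0 over all genes, with a median of 0.76, or 0.64 relative to all genes (adjusted p = 0.672 with an estimated correlation). The 3 wild-type females of the CGI set stood apart, with Dbp at 3.12 to 11.5 CPM against 75.4 and 94.1 CPM in the 2 wild-type females of the LARA set.

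**Figure D3:**
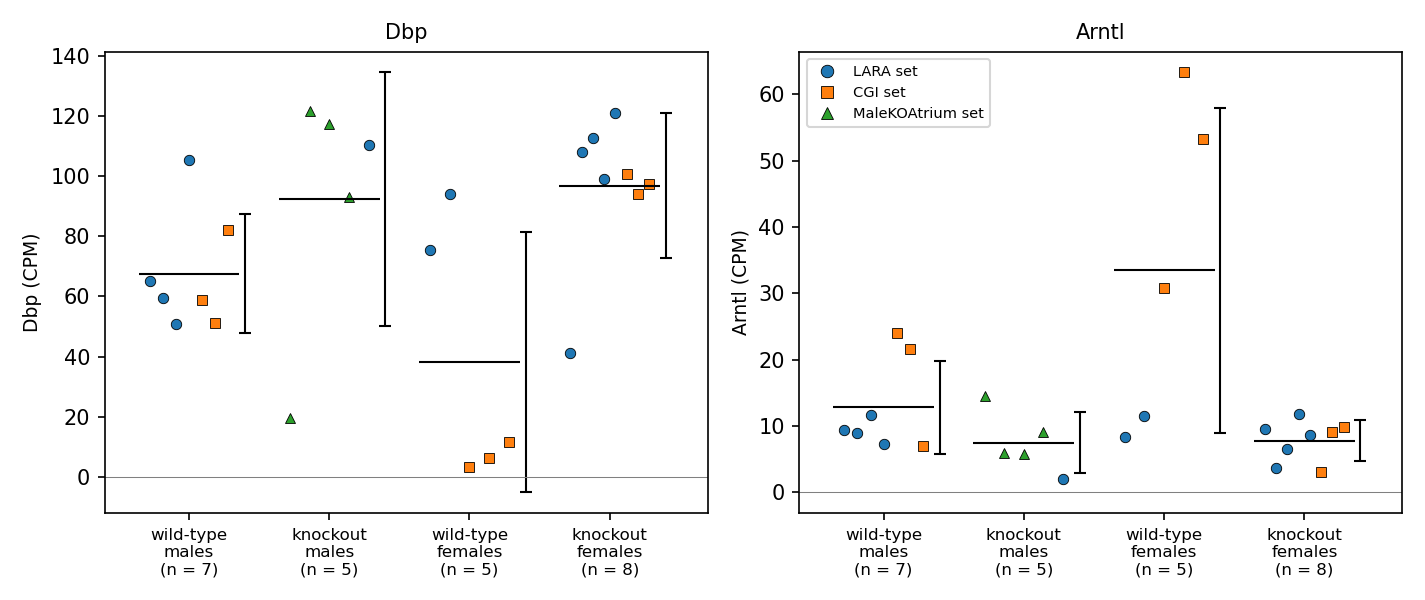
Dbp (left) and Arntl (right) in CPM, 1 point per library, by group, with lines at group means and bars of ± 1 SD. The 3 wild-type females of the CGI set lie lowest in Dbp, at 3.12 to 11.5 CPM, and highest in Arntl, at 30.7 to 63.3 CPM.

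Of the steroid list in females, the glucocorticoid targets Zbtb16 (log2 2.01), Fkbp5 (1.47), the period gene Per1, Hif3a (1.38) and Tsc22d3 (0.81) were the 5 of 14 genes that passed adjusted over the list alone, with 0 over all genes (adjusted p = 0.618 with an estimated correlation). The mean log2 level of this list was lowest in the 3 wild-type females of the CGI set, at 3.20 to 3.73. It was 4.18 and 4.34 in those of the LARA set. Of the knockout females, KF16, KF17, KF20 and KF21 lay above both, at 4.53 to 4.88, and the others lay at 3.98 to 4.31. Zbtb16 was at 73.5, 140 and 167 CPM in knockout females of the CGI set and at 16.7 to 60.8 CPM in those of the LARA set. Wild-type females had at most 31.8 CPM. Within the LARA set the genotypes overlapped, with the list at 4.18 and 4.34 in wild-type and 3.99 to 4.67 in knockout females. Zbtb16 there was at 31.8 CPM in wild-type WF8, with KF15, KF17 and KF18 below it and KF14 and KF16 above it. Of the wild-type males of the CGI set, WM7 had 88.9 CPM, and WM5 and WM6 had 18.2 and 14.2 CPM. These values do not decide how far the difference lies with the 3 wild-type females of the CGI set. Fatty acid oxidation genes had a median of -0.24, or -0.36 relative to all genes (0 of 28 called by either count, adjusted p = 0.433 with an estimated correlation). Erythroid genes had a median of -0.85 and ventricle markers of -0.61, with 0 members called by either count (adjusted p = 0.433 and 0.281 with an estimated correlation). For erythroid genes the name sets went opposite ways, with mean log2 levels of 3.88 and 5.31 in wild-type and 3.58 to 6.40 in knockout females of the LARA set, and of 5.59 to 6.97 (WF10 highest) and 3.87 to 4.73 in the CGI set. In all, camera called 13 lists in females, 4 higher and 9 lower, and 0 were kept (adjusted p = 0.281 to 0.856 with an estimated correlation). Immune cell genes and calcium handling genes were called lower although their medians were 0.02 and 0.05, since the test is relative to all other genes. With median-ratio scaling and quantile normalization the medians were -0.0832 and -0.0981 for immune cell genes, and -0.0771 and 0.00512 for calcium handling genes.

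In males, 62 genes were called, 8 higher and 54 lower in knockouts, 48 of them by at least 2-fold. Genes of the epicardium, the mesothelial sheet that covers the heart, fell together. The males also differed in the right atrium marker Bmp10, at 0.433 to 1.25 CPM in WM1 to WM3, 1999 to 6180 CPM in the other wild-type males and 4950 to 7597 CPM in the knockout males other than KM01. Lrrn4 fell from 116 ± 26.6 CPM (SD, n = 7) to 29.9 ± 11.7 (n = 5; log2 -1.96 ± 0.29 SE, limma adjusted p = 8.12e-04), the keratin gene Krt8 by 2.27 on the log2 scale, the uroplakin gene Upk3b by 1.82, Krt19 by 1.62 and Upk1b by 0.98. Of the 12 epicardial and mesothelial genes 5 fell, and 11 adjusted over the list alone, with a median of -1.20 (adjusted p = 0.0493 with an estimated correlation, fry adjusted p = 0.00186). Tcf21, at 0.19, was the member with a difference above 0. With limma the knockout effect on these genes was not shown to differ between the sexes, with an interaction of 1.79 for Lrrn4 (limma adjusted p = 0.319) and 1.54 for Krt8 (adjusted p = 0.475).

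Other genes that fell in males were Spon2, a secreted matrix protein gene (36.3 ± 15.5 CPM SD, n = 7, to 5.37 ± 1.26, n = 5, limma adjusted p = 5.70e-04), the sulfotransferase gene Chst4 (log2 -1.99), the endocytic receptor gene Lrp2 (-1.89), the Hippo pathway gene Wwc1 (-1.84), complement C3 (-1.75) and the tight junction gene Cldn15 (-1.72). Apln, which encodes the peptide apelin, rose from 2.25 ± 0.73 to 15.6 ± 8.94 CPM (log2 2.12 ± 0.36 SE, adjusted p = 0.00292), and it was the 1 called gene of the atrial peptide list. The small heat shock protein gene Hspb7, expressed in heart muscle, rose from 504 ± 71.5 to 912 ± 97.3 CPM (log2 0.86). Pmel (log2 1.39), Rasa4 (1.15), Cnksr1 (1.14), the actin-bundling gene Fscn1 (1.07) and Rassf5 (0.88) also rose, and Pmel and Cnksr1 lay at 0 to 1.30 and 0.438 to 1.38 CPM in wild-type males, near the floor of 3 reads. In KM13, the knockout male outside the MaleKOAtrium set, Hspb7 was at 845 CPM and Spon2 at 5.76 CPM, while Apln at 2.97 CPM and Upk3b at 396 CPM lay within the 1.60 to 3.50 and 345 to 515 CPM of wild-type males.

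**Figure D4:**
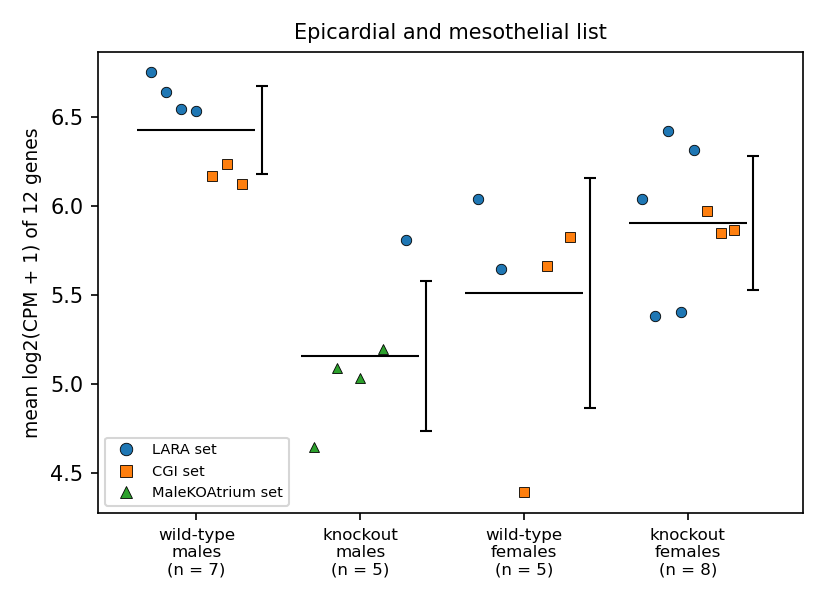
Mean log2(CPM + 1) of the 12 epicardial and mesothelial genes, 1 point per library, by group, with lines at group means and bars of ± 1 SD. Knockout males lie at 5.16 ± 0.42 (n = 5) and wild-type males at 6.43 ± 0.25 (n = 7), and KM13, at 5.81, lies above the other 4 knockout males and below every wild-type male.

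In males the knockout and the MaleKOAtrium set cannot be told apart for 4 of 5 libraries. KM13 has an RA name, while of the wild-type males of its set only WM4 has one and WM1, WM2 and WM3 have LA names. With the set as a term, KM13 is the 1 knockout male left in the contrast. Wild-type males of both the LARA and the CGI set enter it, with the offset between the sets estimated over the groups that they share. Within the LARA set alone, with KM13 against 4 wild-type males, Pam differed by log2 -3.23. Without KM13 548 genes were called, 296 higher and 252 lower, and the count was 23 without KM01, 31 without KM03, 36 without KM05, 25 without KM07, 29 without WM1, 27 without WM2, 30 without WM3, 34 without WM4 and 41 without WM7. Scaling moved the count to 159 (median-ratio) and 211 (quantile), with 61 and 62 of the 62 genes among them. More genes were lower than higher also in edgeR (76 higher and 111 lower) and DESeq2 (270 and 311), but not with arrayWeights in limma (2679 and 1075) or without KM13.

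Camera called 8 lists in males, and the epicardial list was the 1 kept. Cell cycle genes had a median of 1.04, with 8 of 17 higher adjusted over the list alone, among them Rrm2 (1.16), Birc5 (1.37) and Mki67 (1.62). Erythroid genes had a median of 1.46, with 7 of 8 higher adjusted over the list alone. Their mean log2 level was 3.62 to 4.02 in CGI and 5.33 to 6.41 in LARA wild-type males, 5.61 in KM13 and 6.18 to 7.45 in the MaleKOAtrium set. Immune cell genes had a median of 0.41, with 2 of 27 higher adjusted over the list alone. Cardiac stress genes had a median of 0.60, with 4 of 17 higher adjusted over the list alone, among them Nmrk2 (2.07), Xirp2 (1.03) and Tnc (1.47). For these 4 lists 0 members passed over all genes, and adjusted p = 0.638 with an estimated correlation. In the other 3 lists KM01 and KM07 stood highest, with mean log2 levels of cell cycle genes of 5.16 and 4.07 against 2.60 to 3.01 in the other knockout males and 2.05 to 3.39 in wild-type males. Cardiac stress genes were at 8.41 and 7.65 against 6.33 to 6.74 in the other knockout males. Immune cell genes were at 5.47 and 5.16 against 4.70 to 4.90. Oxidative phosphorylation genes had a median of -0.31 (3 of 32 lower adjusted over the list alone, 0 over all genes, adjusted p = 0.681 with an estimated correlation), fatty acid oxidation genes of -0.35 (0 called by either count, adjusted p = 0.839 with an estimated correlation) and endoplasmic reticulum stress genes of -0.21 (0 called by either count, adjusted p = 0.940 with an estimated correlation).

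Female against male in wild type, a check of the sex labels and of sex differences of the atrium, gave 8 called genes. Xist, the RNA that silences the second X chromosome, was at 613 ± 88.0 CPM (SD, n = 5) in females and 1.39 ± 0.92 (n = 7) in males (log2 7.97 ± 0.28 SE, limma adjusted p = 1.09e-16). Kdm6a, which escapes X inactivation, was higher in females (log2 0.90). The Y-linked Ddx3y was at 216 ± 40.1 CPM in males and 1.73 ± 2.15 in females (log2 -6.53). Lower in females were also the drug efflux gene Abcb1b (log2 -1.23), the sphingomyelinase gene Smpd3 (-0.99), the cyclin gene Ccnd1 (-0.93) and Wdfy1 (-0.84). In the LARA set both wild-type females, WF8 and WF9, have RA names, as WM4 does, while WM1 to WM3 have LA names. The set term does not part these names, so sex and name are mixed there. Abcb1b was at 49.1 CPM in WM4 and at 44.0 and 34.0 CPM in WF8 and WF9. The other 3 genes kept a wider gap, with Smpd3 at 40.3 against 29.3 and 25.3 CPM, Ccnd1 at 46.9 against 29.3 and 29.9, and Wdfy1 at 30.4 against 13.8 and 16.1. Eif2s3x (log2 0.68), the B cell gene Cd79b (1.14) and the dystrophin gene Dmd (0.97) did not pass. Pam differed by -0.24 (adjusted p = 0.875).

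The median of all genes lay at -0.107 in this comparison and at 0.0032 after median-ratio scaling, and the called genes were then 3 higher and 4 lower in place of 2 and 6. The count was 2 without WM1, WM2, WF9 or WF12, 3 without WM7 and 4 without WM3. Of 7 X-linked genes that act in or escape X inactivation 2 were higher in females over all genes and 5 adjusted over the list alone (median 0.62, adjusted p = 9.31e-05 with an estimated correlation). The 12 epicardial genes had a median of -0.98 in wild-type females relative to males, with 10 lower adjusted over the list alone and 0 over all genes (adjusted p = 0.0969 with an estimated correlation, fry adjusted p = 0.0173). The other 10 of 12 lists called by camera lost the call (adjusted p up to 0.809 with an estimated correlation). Among them, oxidative phosphorylation genes were called higher with a median of -0.02 and a mean of 0.02, and immediate early genes lower with a median of -0.55.

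Female against male in knockouts rests on KM13 within the LARA set, because the other knockout males share no set with females. KM13 has an RA name, and among the knockout females of its set KF14, KF16 and KF17 have LA names. Xist (log2 5.76 ± 0.51 SE, limma adjusted p = 3.00e-07) and Ddx3y (log2 -5.81 ± 0.74 SE, adjusted p = 2.11e-04) were the 2 called genes. X-linked genes were higher as a list, with 1 of 7 called over all genes and 5 adjusted over the list alone (median 1.19, adjusted p = 0.00361 with an estimated correlation). Genes that did not pass were the zinc finger genes Zfp329 (log2 1.36) and Zfp971 (1.40) and the midline gene Mid2 (1.29), and on the other side Serpina3c (-2.78), Igsf1 (-2.10), Krt14 (-1.98) and the haptoglobin gene Hp (-3.97). Pam differed by -0.04 (adjusted p = 0.995). The other 9 of 10 lists called by camera, fatty acid oxidation (median -0.64) and glycolysis (-0.62) among them, lost the call (adjusted p = 0.124 to 0.668 with an estimated correlation). The median of all genes lay at 0.113 and at -7.93e-04 after median-ratio scaling, with 6 genes higher and 1 lower then called, and 12 genes were called without KM01.

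Whether the knockout effect differed between females and males was tested as an interaction, and 0 of 14457 genes passed with limma, with 1326 at an unadjusted p under 0.05. On the recovered reads 10 genes passed with edgeR and 234 with DESeq2. The genes of smallest p were higher in the female effect for the G protein subunit gene Gng4 (log2 3.31, limma adjusted p = 0.173), Zfp329 (1.48), Zfp738 (1.34), the steroidogenic gene Star (2.64) and Scai (1.57), and lower for the B cell genes Cd79b (-3.08) and Cd79a (-2.59), the creatine kinase gene Ckm (-1.89) and Alas1 (-1.84). Epicardial genes had a median of 1.05, or 0.81 relative to the median of all genes of 0.248 (0.0218 after median-ratio scaling), with 1 of 12 higher adjusted over the list alone and 0 over all genes (adjusted p = 0.496 with an estimated correlation). Pam itself gave 0.20 (adjusted p = 0.936). This test too rests on KM13 for the knockout males. KM13 has an RA name, while WM1, WM2 and WM3 of its set have LA names.

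In the authors' deposited table, 1064 of 14389 genes have a p under 0.05, where 719 would be met by chance. With Benjamini-Hochberg adjustment applied to these p-values here, 9 genes pass, among them Pam, Best3, Spon2, Arxes2, Mfsd14b, Ppip5k2, Arntl and Tbx18. Best3, Arxes2, Mfsd14b, Ppip5k2 and Tbx18 lie outside the rule for named genes and are given because they are part of this count. Ppip5k2, an inositol pyrophosphate kinase gene next to Pam, was at 221 ± 54.1 CPM (SD, n = 5) in wild-type and 505 ± 94.4 (n = 8) in knockout females, and at 222 ± 66.4 (n = 7) and 419 ± 221 (n = 5) in males. Its log2 difference over both sexes was 1.20 ± 0.31 SE in limma (adjusted p = 0.974), with KM01 at 64.9 CPM and the other knockout libraries at 356 to 635 CPM.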

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

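The tests of epicardial genes, of clock genes and of the region around Pam in this part were chosen after the result was seen, while the position of Ppip5k2 and the counts of other splits were planned.

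Ppip5k2, the neighbour of Pam, was higher in 12 of 13 knockout libraries than in every wild-type library (356 to 635 CPM against 135 to 329 CPM), all but KM01 at 64.9 CPM, and Wdfy1, on the same chromosome, was higher in knockout females and was 42.5 to 49.9 CPM in the 4 MaleKOAtrium males and 22.3 CPM in KM13 (wild-type males 24.9 to 44.7), with wild-type females below wild-type males (log2 -0.84). Among the other genes within 20 Mb of Pam, 2 of 118 (1.69%) had p under 0.01 over both sexes, against 76 of 14185 (0.536%) elsewhere (one-sided Fisher's exact p = 0.136), which does not decide whether DNA around the targeted allele differs from wild type. The 2 genes, named because they make up this count, were Utp14b and Per2. Per2 is a clock gene and was at 3.40 to 7.06 CPM in the 3 wild-type females of the CGI set, which stood apart in clock genes. Ppip5k2 lies 24702 bases past the end of Pam and is the next protein-coding gene on the same strand, so transcription of the altered Pam gene may run into it. That test was on the position alone and says nothing of Wdfy1, which lies at 79702262 to 79776143. Open are both explanations for Ppip5k2, which were not tested by reads across the boundary, and for Wdfy1 a response to the loss of Pam or a linked variant, with KM13, a single library, going the other way.

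Epicardial and mesothelial genes were lower in knockout males by a median of 1.20 on the log2 scale. In females the list had a median of 0.31, and of 0.0911 without WF10 and KM01, with WF10 the lowest wild-type female (4.39, others 5.65 to 6.04). Both medians go against a fall of these genes with Pam in both sexes, but they mix libraries of unlike Bmp10. Among females with Bmp10 at 4107 CPM or more, KF15 and KF17 (5.38 and 5.40) lay below WF8 and WF9 (6.04 and 5.65) in the LARA set. In the CGI set KF20 and KF21 (5.85 and 5.87) lay above WF11 (5.66). KM13, the knockout male outside the MaleKOAtrium set, had a mean of 5.81. It lay below the 6.53 to 6.75 of the 4 wild-type males of its set and above the 4.99 ± 0.24 (SD) of the MaleKOAtrium set. Of those wild-type males, WM1 to WM3 have LA names and Bmp10 at 0.433 to 1.25 CPM. Only WM4 (6.53, Bmp10 at 1999 CPM) shares the RA name of KM13 (Bmp10 at 4950 CPM). KM01, with Bmp10 at 46.5 CPM, was the lowest knockout male (4.64), and Lrrn4 kept log2 -1.98 with Bmp10 as a covariate. These values do not decide on the region, since Lrrn4 is 1 gene and KM01 stood apart in other ways. It had a depth of 2494461 reads and 18.5% of CPM from mitochondrial genes. KM13 is the 1 knockout male outside the MaleKOAtrium set. An effect of Pam in males and a difference of that set therefore cannot be told apart. Such a difference could be the region or how much of the outer surface was taken with the atrium. Wild-type females were also lower than wild-type males (median -0.98), and in LARA knockout females the list was 6.04 to 6.42 in KF14, KF16 and KF18, with Bmp10 at 1.26 to 444 CPM, and 5.38 and 5.40 in KF15 and KF17, with 5009 and 4811 CPM, so the amount of these genes may vary with the region taken.

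Clock genes were called as a list between knockout and wild-type females with the preset correlation only (adjusted p = 0.672 with an estimated correlation, 0 of 19 genes over all genes). The clock index, the mean log2 level of 9 genes that include Dbp, Per1 and Nr1d1 minus that of Arntl, Npas2, Clock and Nfil3, was at most -0.964 in the 3 wild-type females of the CGI set and at least 0.891 in the other wild-type libraries compared, the 3 wild-type males of that set and the 2 wild-type females of the LARA set, a gap of 1.86. A collection of these 3 mice at another time of day is a candidate explanation, and times are not given in the sources used here. Within the LARA set the index was 2.83 ± 0.62 (SD) in 6 knockout and 2.26 ± 0.27 in 6 wild-type libraries (exact permutation p = 0.0779). The knockouts were 5 females and 1 male and the wild types 2 females and 4 males, so this test mixes genotype with sex. WM1 to WM3 among them also have LA names and low Bmp10. The CGI knockout females, at 2.69 to 2.89, lay above the CGI wild-type males (0.891 to 2.55), again across the sexes. A shift of the clock with the loss of Pam was thus not decided and stays open.

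Several libraries lay far from the others of their group. Of 69 groups of values tested with Dixon's test 13 had such a library, where 3.45 would be met by chance in independent, normally distributed groups. The groups were not independent, since several shared a library or a gene list, and their genes were called in these same data. The excess over chance is therefore not measured. Among wild-type females, WF10 had a depth of 2246887 reads (next 6392633), 30.2% of CPM from mitochondrial genes (next 12.6%) and Smpd3 at 11.6 CPM (next 25.3). Among knockout males, mitochondrial genes gave 18.5% in KM01 (next 9.93%), and KM13 had Cldn15 at 71.3 CPM (next 29.5), Krt19 at 87.3 (next 23.7), Krt8 at 18.9 (next 8.40), Upk3b at 396 (next 124) and Xist at 9.28 (next 3.09). Spon2 was at 3.19 CPM in KM05 (next 5.56), Rasa4 at 5.42 CPM in WM1 (next 3.38), Kdm6a at 73.7 CPM in WF12 (next 64.8) and Ddx3y at 6.74 CPM in the knockout female KF14 (next 0.366).

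The interaction of knockout and sex rests on KM13 for the knockout males, and it was called for 13 lists with the preset correlation and for 0 with an estimated correlation (adjusted p = 0.0553 to 0.851 with an estimated correlation). KM13 had the highest mean log2 level of the 25 libraries for fatty acid oxidation (7.71) and glycolysis (7.78), while over the 5 knockout males fatty acid oxidation genes had a median difference of -0.35 from wild type, so the knockout male side of these values is 1 library. Lower in the female effect were fatty acid oxidation (median -0.76, preset adjusted p = 4.21e-15, 6 of 28 adjusted over the list alone and 0 over all genes), glycolysis (-0.85, 6.39e-13, 5 of 21 adjusted over the list alone and 0 over all genes), oxidative phosphorylation (-0.31, 5.16e-08), sarcomere genes (-0.23, 2.51e-04), erythroid genes (-1.26, 0.00198), adipocyte genes (-0.39, 0.00198) and ventricle markers (-1.27, 0.00608). Higher were immediate early genes (1.35, 3.61e-05) and epicardial genes (1.05, 0.00109). Called lower with a median near 0 or above it were immune cell genes (median -0.03, mean -0.30, adjusted p = 0.00164), hypoxia targets (-0.00, mean -0.19, 0.0241), calcium handling genes (0.04, mean -0.07, 0.0260) and skeletal muscle genes (-0.03, mean -0.36, 0.0260).

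Chance as the origin of the counts was tested with 100 splits of the libraries per comparison, the real one included. As many genes as the real split were called in 3 splits over both sexes (real 1, highest other 1), in 2 in females (real 2, highest other 4) and in 1 between wild-type sexes (real 8, highest other 2). These lie under the limit of 5 in 100 splits, and between wild-type sexes the real count was above that of every other split. Over both sexes, however, 2 other splits called as many genes as the real one and in females 1 other split called more. The real genes were Pam over both sexes and Pam and Wdfy1 in females. Counts of 1 and 2 thus cannot exclude chance for any gene other than Pam. The splits were also drawn without regard to the name set. In males 7 splits (real 62, highest other 2075) and between knockout sexes 7 splits (real 2, highest other 2283) gave as many, so chance cannot be excluded there, and the high counts point to a structure of the samples. With the 4 MaleKOAtrium libraries kept together and KM13 exchanged for 1 wild-type male, 1262 genes were called with WM5, 527 with WM6, 283 with WM4, 50 with WM7, 2 with WM1, 1 with WM3 and 0 with WM2 (limma). The counts did not follow the name set of the exchanged male, since WM4 is of the LARA set like WM1 to WM3. They were high for WM4 to WM7, with Bmp10 at 1999 to 6180 CPM, and low for WM1 to WM3, with Bmp10 at 0.433 to 1.25 CPM. For the interaction 100 splits gave at least the real count of 0 (highest other 1).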

How the results depend on the processing

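The fits with edgeR, DESeq2, Bmp10 as a covariate, without WF10 and KM01 and without the 3 wild-type females of the CGI set were chosen after the result was seen, and the other alternatives were planned. Of the main values and counts, 144 stayed within the limits set, 85 moved and 3 became weaker. Of the values of named genes, 2006 kept direction and side of the threshold, 261 became weaker, 110 stronger and 17 reversed. Where no cause is given below, the cause was not tested. The filter of 1 CPM removed 0 genes, so leaving it out tested nothing.

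Pam kept its direction within name sets, at log2 -3.39 in LARA females (exact permutation p = 0.0952), -3.24 in CGI females (exact p = 0.1) and -3.23 in LARA males (exact p = 0.4), each the smallest p that so few libraries can give.

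Over both sexes (1 gene) the count was 21 with arrayWeights, 24 with the CGI set alone, 2 without the MaleKOAtrium set, 3 with DESeq2, 2 without WF10 and KM01, and 1 to 3 with each library left out. The CGI set holds no knockout males, so its 24 genes are those of the comparison in females. In females (2 genes) it was 1 with median-ratio scaling, 1 with quantile normalization, 1 with no name set term, 1 with the LARA set alone, 1 with edgeR, 1 without the 3 wild-type females of the CGI set, 26 with arrayWeights, 24 with the CGI set alone, 13 with DESeq2, and 1 to 2 with each library left out.

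In males (62 genes) the count was 159 with median-ratio scaling, 211 with quantile normalization, 3754 with arrayWeights, 187 with edgeR, 581 with DESeq2, 101 with Bmp10 as a covariate and 40 with only the compared groups. It was 1 with the name set as a term, 1 with the set in 4 levels, 1 with the LARA set alone and 9 with edgeR with the name set as a term, where 1 knockout male is left to compare and is assumed to vary like the other groups. With each library left out it was 23 to 548. Library numbers recur between wild-type and knockout males, and with the number as a replicate block the count was 16. Whether the numbers pair the libraries is not decided by their correlations, which went both ways. Of 4 knockout libraries 2 correlated best with the wild-type library of their own number and 2 with another. The correlations within a number were 0.236, -0.204, 0.246 and 0.0669 for the numbers 1, 3, 5 and 7.

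Between wild-type sexes (8 genes) the count was 57 with arrayWeights, 2 with the set in 4 levels, 3 with the LARA set alone, 14 with the CGI set alone, 16 without the MaleKOAtrium set, 80 with DESeq2, 15 without WF10 and KM01, and 2 to 10 with each library left out. Between knockout sexes (2 genes) it was 36 with a pseudocount of 0.1, 7 with median-ratio scaling, 8 with quantile normalization, 727 with arrayWeights, 14 with no name set term, 4 with only the compared groups, 9 with edgeR, 173 with DESeq2, 27 with Bmp10 as a covariate, 85 without WF10 and KM01, and 2 to 12 with each library left out. For the interaction (0 genes with limma, 1326 at an unadjusted p under 0.05) it was 12 with a pseudocount of 0.1, 591 with arrayWeights, 23 with no name set term, 10 with edgeR, 234 with DESeq2, 7 with Bmp10 as a covariate, 6 without WF10 and KM01, and 0 with each library left out. Without KM13 the comparison of knockout sexes and the interaction could not be fitted with the name set and were not run.

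Pam, which did not pass between sexes, changed sign there. In wild type (-0.24) it was 0.0913 with arrayWeights, 0.20 with the LARA set alone, 0.13 without WF10 and KM01, and -0.40 to 0.13 with each library left out. In knockouts (-0.04) it was 0.0140 with quantile normalization, 0.0602 with the set in 4 levels, 0.0361 with no name set term, 0.0420 with only the compared groups, 0.27 with Bmp10 as a covariate, and -0.10 to 0.00823 with each library left out. In the interaction (0.20) it was -0.0548 with median-ratio scaling, -0.23 with arrayWeights, -0.10 with edgeR, -0.10 with DESeq2, -0.23 without WF10 and KM01, and -0.23 to 0.36 with each library left out. Krt14 between knockout sexes (-1.98) was 0.0423 with no name set term.

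Gene lists called with the preset correlation were 6 over both sexes, 13 in females, 8 in males, 12 between wild-type sexes, 10 between knockout sexes and 13 for the interaction. With an estimated correlation they were 0, 0, 1, 1, 1 and 0, and with fry 0, 0, 1, 2, 1 and 0. With the name set term left out, or in males added, they were 9, 9, 10, 9, 10 and 9, of which 3, 9, 4, 9, 4 and 6 were among those first called. Without WF10 and KM01 they were 6, 7, 6, 10, 8 and 9, of which 2, 4, 3, 5, 8 and 8 were among those first called.

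Depth limits genes of few reads, since 3 reads stand for 1.34 CPM in WF10 and 0.370 CPM in KM07.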

Other observations

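The tests in this part were all chosen after the result was seen. Atrial chamber genes varied between libraries of the same group. Bmp10, the transcription cofactor gene Cited1 and the potassium channel subunit gene Kcnip2 had lower means in libraries whose names begin with LA than in those that begin with RA, with Bmp10 at 815 ± 1958 CPM (SD, n = 6) and 3820 ± 2200 CPM (n = 6, exact permutation p = 0.00866) Cited1 at 3.39 ± 1.16 and 6.98 ± 1.74 CPM and Kcnip2 at 15.5 ± 8.37 and 38.8 ± 12.9 CPM (exact permutation p = 0.00649 for both). Cited1 was on the list of left and Bmp10 on that of right atrial markers, so the lists do not settle what the names mean. None of 25 genes tested passed after adjustment (exact permutation tests, 0 under 0.05, lowest adjusted p = 0.0722), and what LA and RA stand for is not given in the sources used here.

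KF17, of the LA names, had Bmp10 at 4811 CPM, where the other 5 had 0.433 to 76.5 CPM, so that the mean of the LA names comes almost wholly from it, and KF18, of the RA names, had it at 444 CPM. Whether these 2 names were exchanged was not tested, and both means would change if they were. WF10 had the lowest Pam of the wild-type libraries, at 1409 CPM, with Myl2 at 4724 CPM and the atrial light chain gene Myl7 at 1127 CPM. KM01 had Nppb at 4686 CPM, where the other knockout males had 393 to 1319 CPM.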
